A study of Rattus norvegicus with 32 samples.

How the data were processed

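The measurements were RNA sequencing libraries of the rat nucleus accumbens shell, 32 in all, sorted into 4 groups of 8 by the treatment label. RNA was extracted with a Zymo kit. It was sequenced on an Illumina instrument after polyA selection by a service laboratory, per the labels' protocols. The labels give no sex, age, batch or animal for a library. Library numbers used here follow the order of deposition, so they pair no libraries across groups.

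The values are counts of reads per gene as the authors deposited them, whole numbers for 34322 gene symbols. The submitters' processing notes name STAR (an aligner), featureCounts (a read counter) and DESeq2 (a test), with versions not given in the sources used here, and the genome builds mRatBN7.2 and Rnor_6.0 with no role for either. Whether reads were counted by strand is not given in the sources used here, so counts of genes that overlap, and of near-identical copies such as ribosomal protein genes, are uncertain. Of the symbols, 27234 (79.3%) matched a table of gene names of the assembly GRCr8, which was used for names alone. Every column of the table belonged to a library by its title, and 0 counts lacked a gene name. No pair of libraries held identical values: over the 112 pairs within groups, a chi-square test on genes with a count of at least 10 gave 5.24 to 102.7 per degree of freedom.

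Counts were tested with edgeR 4.0.16 in R 4.3.3. The function filterByExpr by group kept 17059 genes and left out 17263 with low counts, and TMM scaled the libraries. A quasi-likelihood model with a mean per group was fitted to all 32 libraries, which share 1 estimate of the spread (common biological coefficient of variation 0.215, median 0.164). Contrasts gave the cue effect within vehicle and within CBD, the CBD effect within each cue, their interaction and the mean effects of cue and CBD. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. A gene or list given as at a value has that log2 fold change (for a list, the median). Means and SDs are in CPM, counts scaled to a common library size, and log2 CPM carried a prior count of 2. Total counts were 578.3 M in all, and the 20 most abundant genes took 4.16 to 5.29% of them. The first and second principal components of the log2 CPM held 27.1% and 13.7% of the variance.

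Lists of genes for mitochondrial, lipid, cannabinoid, stress, neuronal and glial functions and for neighbouring tissues were written down, with the design and the other settings to be tried, before the data were examined. Each list with measured members was compared with all other genes by camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, and adjusted over the 30 lists tested within each comparison. Beside it stand camera with an estimated correlation, fry, and the number of members past the threshold adjusted over the list alone. An exact permutation test, 2-sided and run in R, was also made of each list's mean log2 CPM per library. The protein-coding genes of the mitochondrial genome and Ttr are not analysed here.

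Genes were picked for naming by a fixed rule, and not all are printed. In each comparison these are up to 10 higher and 10 lower genes by p among those past the threshold. Where fewer than 5 pass, the 5 with the smallest p are given as values with no claim of change. Named too are per list the 2 members with the smallest p and up to 4 past the threshold adjusted over the list alone. A preset group of genes, such as Fos, Cnr1, Fads1, Cox4i1, Drd1 and Mbp, may be given as values whatever their p. Genes known only by a locus number were counted and not named. Markers of tissue outside the lists, such as Alb and Plin1, were chosen after their values were seen, and so were the hepatocyte and adipocyte lists.

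The opposite direction of the CBD and cue effects was measured as a correlation and covariance of log2 fold changes across genes, with the 8 shared libraries split 4 and 4 in all ways, and set beside 100 simulations of unchanged groups. The scripts were tested on simulated data with the real means and library sizes and 17059 genes, 50 genes changed at each of 4 folds. At folds of 1.3, 1.5, 2 and 4 the model recovered 40, 46, 82 and 92% for the cue in vehicle libraries, 32, 48, 76 and 98% for CBD with the anxiety cue, 22, 68, 82 and 98% for CBD with the neutral cue, and 28, 58, 88 and 98% for the cue in CBD libraries. Of the calls in these comparisons, 5.8, 3.79, 6.85 and 4.9% were false. A gene that changed 2-fold could thus be missed, and at 1.5-fold 32 to 54% were. Depth was not varied in these simulations. Besides the list set to change, at most 1 passed camera, against medians of 8 to 12 in splits of the real libraries. The rates above may thus not carry over.

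Other settings fixed in advance were DESeq2's size factors within edgeR, DESeq2 1.42.0 itself, no filter on low counts, a filter of 1 CPM in 8 libraries, robust estimation and voom with quality weights. They also included 5 surrogate variables (sva 3.50.0) and covariates for tissue composition (the mean log2 CPM of the cortical, septal, choroid plexus and oligodendrocyte lists). Further ones were a term for low against high title numbers (up to 19, or 22 and above), only the 16 libraries compared, and each library left out in turn. Alternatives added after seeing the data were covariates for liver and fat transcripts, alone and with tissue composition, DESeq2 with each set of covariates, the composition covariates without the list tested where it is 1 of them, and each library left out in turn for the lists. Fits were also made without 3 libraries in doubt, without libraries with Alb of 20 CPM or more, with Plin1 of 5 CPM or more, or with Slc17a6 of 18 CPM or more. The limit for Slc17a6 was set between 16.8 and 20 CPM after its values per library were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.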

Results

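Polyadenylated RNA was measured as counts per gene in 32 libraries from the nucleus accumbens shell of rats. This is the medial part of the ventral striatum, and its main neurons are GABAergic medium spiny neurons. The rats had received shocks in fear conditioning, paired with either a neutral cue or the odour of lemon (here the anxiety cue), and the cue was present later in tests of anxiety. Cannabidiol (CBD, a non-intoxicating compound of the cannabis plant) or vehicle came before those tests, and the tissue was collected after a last shock. The 4 groups, each of 8 libraries, were vehicle with the neutral cue, CBD with the neutral cue, vehicle with the anxiety cue and CBD with the anxiety cue. Total counts per library ranged from 11.65 to 24 M. The labels do not state that each library came from a separate rat. P-values therefore measure only the spread between these libraries, part of which may be technical.

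Markers of neighbouring tissue differed between libraries of the same group. Slc17a6, the vesicular glutamate transporter of subcortical neurons, was 20 CPM (counts scaled to library size) or more in 6 libraries. These were vehicle neutral-cue libraries 4, 7 and 8, vehicle anxiety-cue library 5 and CBD anxiety-cue libraries 2 and 7. Drd1, the dopamine receptor of direct-pathway medium spiny neurons, was 182.8 CPM or less in those 6 libraries and 258.2 CPM or more in the other 26. CBD neutral-cue library 6 held 877 CPM of Slc17a7, the vesicular glutamate transporter of cortex, against 62.3 CPM or less in the others. Rn45s, the ribosomal RNA precursor, and Rpph1, the RNA of ribonuclease P, were at 1732 and 36.6 CPM in vehicle neutral-cue library 8. Mitochondrial ribosomal RNA took its largest share, 1.14% of counts, in vehicle neutral-cue library 6.

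Transcripts of liver and of fat were present at low levels in 20 libraries. Alb, the gene of serum albumin, was between 32.4 and 226 CPM in 10 libraries and at most 9.31 CPM in the rest. Plin1, the perilipin of fat cells, was between 6.16 and 42.6 CPM in 10 other libraries and at most 1.99 CPM elsewhere. The libraries with high Alb numbered 0 in vehicle neutral cue, 4 in CBD neutral cue, 2 in vehicle anxiety cue and 4 in CBD anxiety cue. Those with high Plin1 numbered 5, 0, 3 and 2. Over drug these were 8 CBD and 2 vehicle libraries for Alb, and the reverse for Plin1 (Fisher's exact test, 2-sided, p = 0.0538 for each).

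**Figure D1:**
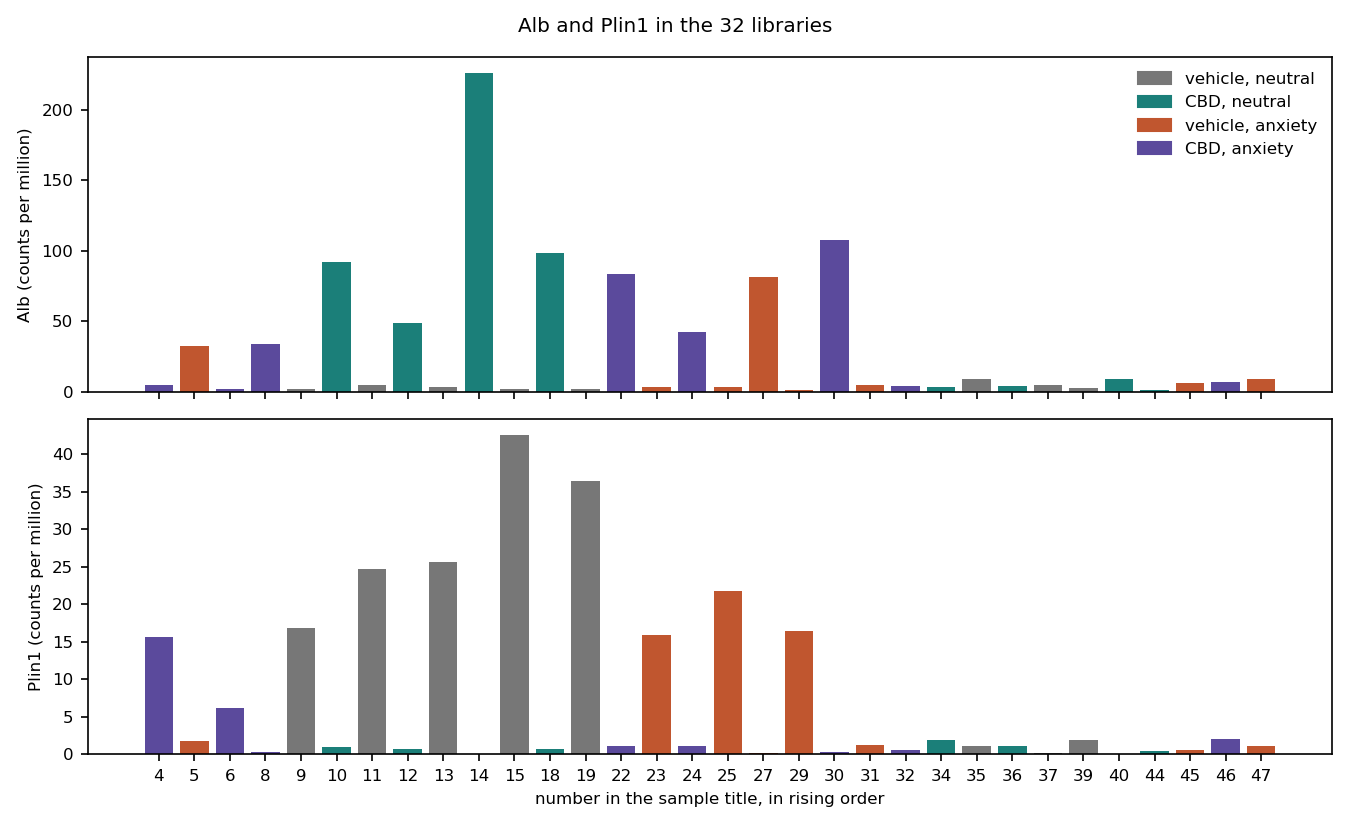
Alb (upper panel) and Plin1 (lower panel) in CPM in each of the 32 libraries, by rising number in the sample title, coloured by group. Alb reaches 226 CPM and Plin1 42.6 CPM, no library is high in both, and the libraries numbered 31 and above are high in neither.

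The effect of the anxiety cue without drug was read from vehicle libraries, anxiety cue against neutral cue. Nuclear genes of the mitochondrial respiratory chain fell as a group with the anxiety cue. The 36 measured subunits of complex I, the entry point of electrons from NADH, had a median log2 fold change of -0.165, with 35 of 36 below 0. The 41 subunits of complexes II to V had a median of -0.156, with 41 of 41 below 0. Camera gave these lists adjusted p = 5.44e-10 and 5.99e-10, and adjusted p = 0.465 for each with an estimated correlation. Random regroupings of these libraries passed a median of 10 of 30 lists. Ndufa8, a complex I subunit, was 62.0 ± 12.2 CPM in neutral-cue and 48.4 ± 8.59 CPM in anxiety-cue libraries (SD, n = 8), a log2 fold change of -0.36 (SE 0.106). The Rieske protein gene of complex III, Uqcrfs1, was at -0.21 (SE 0.068). Cox4i1 of cytochrome oxidase was at -0.17 (SE 0.082). Leaving out neutral-cue library 6 gave medians of -0.0985 for complex I and -0.0972 for complexes II to V, both still past the threshold, and put Cox4i1 at -0.102.

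Other mitochondrial lists fell too with the cue in vehicle libraries. These were mitochondrial ribosomal proteins (median -0.109, 64 of 75 below 0), enzymes of the tricarboxylic acid cycle (-0.105, 21 of 22) and genes of mitochondrial import and dynamics (-0.0892, 25 of 36). Their camera adjusted p were 3.4e-08, 0.000315 and 0.0172, with adjusted p = 0.465 for each with an estimated correlation. Sdhc, shared by complex II and the cycle, was at -0.22 (SE 0.084). The mitochondrial ribosomal median was -0.0569 without neutral-cue library 6, and that of the cycle -0.055 without neutral-cue library 4. The call for import and dynamics ended without neutral-cue library 6 (adjusted p = 0.214) or anxiety-cue library 3 (0.0556).

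Lipid genes fell as well in vehicle libraries with the anxiety cue. The list of linoleic acid and polyunsaturated fatty acid metabolism had a median of -0.163, with 30 of 38 members below 0. Beta oxidation of fatty acids had a median of -0.131, with 19 of 24 below 0, and cholesterol synthesis -0.221, with 21 of 22 below 0. Camera adjusted p were 0.000358, 0.000536 and 3.2e-05, against adjusted p = 0.354, 0.465 and 0.465 with an estimated correlation. Scd2, a stearoyl-CoA desaturase, was at -0.24 (SE 0.081). Fads1, the delta-5 desaturase, was at -0.20 (SE 0.098). Without neutral-cue library 4 the cholesterol median was -0.112 and Fads1 was at -0.121.

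Stress lists fell in the same libraries, but glucocorticoid responsive genes (-0.0146, camera adjusted p = 0.989) did not pass. Chaperones and genes of the unfolded protein response had a median of -0.176, 25 of 28 below 0, and 11 of them passed when adjusted over the list alone. Manf, of the endoplasmic reticulum, was at -0.28 (SE 0.079). The oxidative stress list had a median of -0.124, 24 of 29 below 0, and 4 members passed adjusted over the list alone. They were the uncoupling protein gene Ucp2 (-0.63, SE 0.161), the peroxiredoxin gene Prdx5, the thioredoxin gene Txn1 and the secreted glutathione peroxidase gene Gpx3 (-1.12, SE 0.381). Gpx3 was -0.70 without neutral-cue library 4. For chaperones and oxidative stress camera gave adjusted p = 5.63e-09 and 3.38e-06, and adjusted p = 0.354 for each with an estimated correlation. Cytosolic ribosomal proteins fell with a median of -0.15, 60 of 60 below 0 (camera adjusted p = 6.21e-08; adjusted p = 0.503 with an estimated correlation). Their call ended without neutral-cue library 6 (median -0.0324, adjusted p = 0.149).

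Neuronal markers moved in the same comparison. Medium spiny neuron markers rose, with a median of 0.443 and 29 of 29 above 0 (camera adjusted p = 3.67e-07; adjusted p = 0.465 with an estimated correlation). The transcription factor gene Bcl11b was at 0.44 (SE 0.204). Adcy5, the striatal adenylyl cyclase gene, was at 0.50 (SE 0.255). The dopamine receptor genes Drd1 and Drd2 were at 0.51 (SE 0.291) and 0.46 (SE 0.279). Interneuron markers fell with a median of -0.499, 15 of 20 below 0 (camera adjusted p = 0.0344; adjusted p = 0.465 with an estimated correlation). That call held in 26 of 32 removals of 1 library (highest adjusted p 0.0971, without neutral-cue library 8). Its median was -0.264 without neutral-cue library 4 and -0.3 without library 8 of that group.

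Glial and vascular markers moved as well. Astrocyte markers (median -0.182, 19 of 20 below 0), microglia markers (-0.18, 20 of 21), oligodendrocyte markers (-0.123, 20 of 21) and their precursors' markers (-0.133, 11 of 12) fell. Camera adjusted p, in that order, were 0.000122, 3.47e-05, 0.00534 and 0.00689, and adjusted p = 0.465, 0.465, 0.595 and 0.496 with an estimated correlation. The oligodendrocyte median was -0.0759 without neutral-cue library 4 and -0.228 without anxiety-cue library 5. It was -0.07 without anxiety-cue library 8, which ended the call (adjusted p = 0.0862). Endothelial and mural markers rose with a median of 0.123, 18 of 22 above 0 (camera adjusted p = 0.00534; adjusted p = 0.496 with an estimated correlation). They did not pass without neutral-cue library 1 or 6 or anxiety-cue library 5 (adjusted p = 0.0516, 0.142 and 0.107; median 0.0642 without neutral-cue library 6). With covariates for tissue composition the median was 0.013 for medium spiny neurons (camera adjusted p = 0.823). The oligodendrocyte, septal, cortical and choroid plexus lists are themselves these covariates, so each of them and its genes were fitted throughout with the other 3. Oligodendrocytes were then at 0.0322 (0.639). The full fit gave -0.142 for complex I, -0.155 for complexes II to V, -0.106 for chaperones and -0.0907 for polyunsaturated fatty acid metabolism. It left -0.0467 for the tricarboxylic acid cycle, -0.0902 for cholesterol synthesis and -0.078 for astrocytes. The calls for interneurons (-0.0797, camera adjusted p = 0.717) and oligodendrocyte precursors (-0.0322, 0.305) ended in it. Of the 35 genes picked for naming in this comparison, 13 moved by over 1.5 times or turned with these covariates. Among them Drd1 was at 0.0581, Adcy5 at 0.101, Gpx3 at -0.491 and Sdhc at -0.109.

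Single genes did not pass an adjusted p of 0.05 for the cue in vehicle libraries in edgeR, DESeq2 or voom with quality weights. Of 17059 genes edgeR called 0, with 2175 at an unadjusted p under 0.05 (1094 higher and 1081 lower, 853 expected by chance). With covariates DESeq2 called 16 (composition), 0 (liver and fat) and 33 (both), and edgeR called 19 without libraries high in Slc17a6 and 2972 without those high in Plin1. The genes with the smallest p, each at an adjusted p of 0.353, included Rpph1 (-4.39, SE 0.899, but -1.23 without neutral-cue library 8). Mideas, of a histone deacetylase complex, was at 0.29 (SE 0.063). Mcub, a regulator of calcium entry into mitochondria, was at -1.31 (SE 0.315). The edgeR count at unadjusted p was 1255 without neutral-cue library 4, 4326 without anxiety-cue library 5, and 1186 with composition covariates.

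Cannabinoid and activity genes did not pass as lists for the cue in vehicle libraries. The endocannabinoid list had a median of -0.0321 (camera adjusted p = 0.513). Its 1 member past the threshold adjusted over the list alone was Abhd12, a hydrolase of the endocannabinoid 2-arachidonoylglycerol (-0.18, SE 0.052). The CB1 receptor gene Cnr1 was at -0.68 (SE 0.369), but at -0.315 without neutral-cue library 4 and at -0.204 with composition covariates. Immediate early genes, a readout of recent neuronal activity, had a median of 0.101 (camera adjusted p = 0.359). Fos was at -0.18 (SE 0.278), Arc at 0.36 (SE 0.401) and Egr1 at 0.39 (SE 0.258). Removal of 1 library put Fos between -0.348 and -0.0413 and Arc between 0.114 and 0.564. Composition covariates turned Fos and Arc (0.117 and -0.089) and put Egr1 at 0.112.

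**Figure D2:**
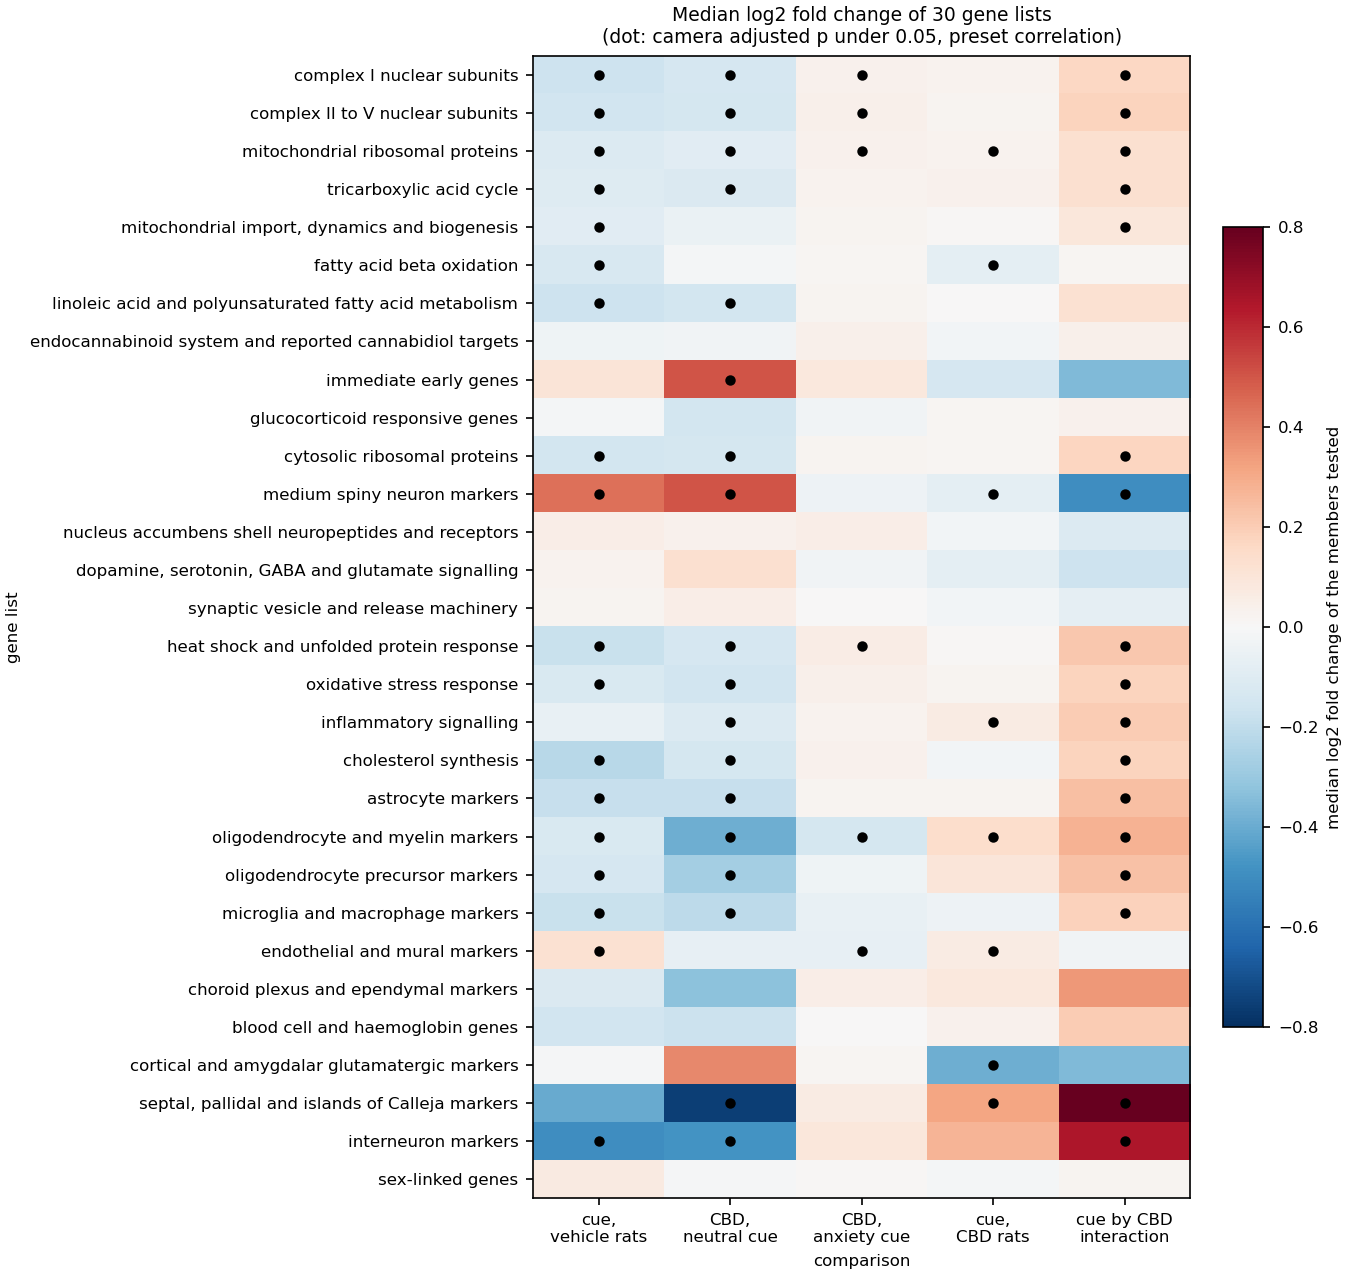
Median log2 fold change of the measured members of 30 gene lists in 5 comparisons (colour scale from -0.8 to 0.8; a dot marks a camera adjusted p under 0.05 with the preset correlation). Complex I has a median of -0.165 for the cue in vehicle libraries, -0.133 for CBD with the neutral cue and 0.0374 for CBD with the anxiety cue.

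The effect of CBD with the anxiety cue was read from CBD against vehicle libraries with that cue. Of the 5 mitochondrial lists 3 were slightly higher with CBD. Complexes II to V rose with a median log2 fold change of 0.0405, 40 of 41 above 0, complex I with 0.0374, 31 of 36, and mitochondrial ribosomal proteins with 0.0358, 54 of 75. Camera gave them adjusted p = 0.00141, 0.0453 and 0.00141, and adjusted p = 0.83 for each with an estimated correlation. The tricarboxylic acid cycle (0.0287, camera adjusted p = 0.34) and import and dynamics (0.0193, 0.473) did not pass. Uqcrfs1 was 65.6 ± 4.34 CPM with vehicle and 70.5 ± 5.95 CPM with CBD (SD, n = 8; 0.10, SE 0.068). Cox4i1 was at 0.018 (SE 0.082).

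These mitochondrial calls depended on single libraries. Those for complexes II to V and for mitochondrial ribosomal proteins ended without vehicle library 3 (adjusted p = 0.503 and 0.255; medians 0.0145 and 0.0203). They also ended without CBD library 7 (0.0814 for each; 0.0266 and 0.025) or 8 (0.38 and 0.0939; 0.0161 and 0.0305). The complex I call held in 20 of 32 removals of 1 library. Its adjusted p was highest, at 0.912, without vehicle library 3. The complex I median ranged from 0.00752 without CBD library 8 to 0.0608 without vehicle library 5. Cox4i1 lay between -0.0206 and 0.0484 over the removals. Composition covariates raised the median of complexes II to V to 0.0641.

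Chaperones and unfolded protein response genes rose with CBD under the anxiety cue, with a median of 0.0598 and 24 of 28 above 0 (camera adjusted p = 0.00053; adjusted p = 0.83 with an estimated correlation). Their median was 0.101 without vehicle library 5 and 0.0393 without vehicle library 7. Oligodendrocyte and myelin markers fell with a median of -0.139, 18 of 21 below 0, and endothelial and mural markers with -0.0671, 18 of 22 below 0. For these, camera adjusted p were 0.000585 and 0.0138, with adjusted p = 0.83 for each with an estimated correlation. Mog was at -0.24 (SE 0.150) and Mbp at -0.17 (SE 0.154). The oligodendrocyte call ended without vehicle library 5 (-0.0554, adjusted p = 0.422), CBD library 5 (-0.0847, 0.151) or CBD library 8 (-0.0864, 0.188). Its median was -0.211 without CBD library 2 and -0.243 with the other composition covariates (1.54e-16), where Mbp was at -0.262 and Mog at -0.346. The endothelial call held in 27 of 32 removals (highest adjusted p 0.336, without vehicle library 5). Its median was then -0.0436, and that removal put Mog at -0.152 and Mbp at -0.0728. In the composition fit the endothelial median turned (0.0238, adjusted p = 0.877) and chaperones no longer passed (0.0359, 0.0545).

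Lipid, cannabinoid and neuronal lists did not pass for CBD with the anxiety cue. Polyunsaturated fatty acid metabolism had a median of 0.0234 (22 of 38 above 0, camera adjusted p = 0.612), beta oxidation 0.0174 (0.991) and the endocannabinoid list 0.0376 (0.473). Immediate early genes were at 0.0827 (24 of 30 above 0, 0.12) and medium spiny neuron markers at -0.0395 (0.612). Fads1 was at 0.041 (SE 0.098). Faah, the anandamide hydrolase, was at -0.14 (SE 0.082). Cnr1 was at 0.34 (SE 0.369). Drd1 was at -0.066 (SE 0.290). Fos was at 0.25 (SE 0.278), Arc at 0.10 (SE 0.399) and Ucp2 at 0.33 (SE 0.161). Removal of 1 library put Fos between 0.159 and 0.425, Arc between -0.0259 and 0.346, Drd1 between -0.205 and 0.0486 and Fads1 between 0.00577 and 0.0862. Ucp2 was at 0.166 without CBD library 2 and Cnr1 at 0.53 without vehicle library 5. Composition covariates turned Drd1 (0.0634) and put Cnr1 at 0.177, Arc at 0.365 and Fads1 at 0.101.

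For CBD with the anxiety cue edgeR called 0 single genes, with 270 at an unadjusted p under 0.05 (128 higher and 142 lower, 853 expected by chance). DESeq2 and voom with quality weights called 0. With covariates DESeq2 called 17 (composition), 1 (liver and fat) and 21 (both). The edgeR count at unadjusted p ranged from 229 without vehicle library 7 to 566 without vehicle library 5, and was 564 with composition covariates. Among the genes with the smallest p, each at an adjusted p of 1, Zfp438 was at -0.34 (SE 0.084). The secretogranin gene Scg2, of dense-core vesicles, was at 0.30 (SE 0.091, but 0.182 with composition covariates).

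Whether CBD moved transcripts back from their level under the anxiety cue was read across genes. Log2 fold changes of CBD with that cue were set beside those of the cue in vehicle libraries. Because both use the 8 vehicle anxiety-cue libraries, these were split 4 and 4, with 1 part for each comparison. Over 70 such splits the mean correlation across 17059 genes, which are not independent replicates, was 0.0695 (SD 0.221, range -0.273 to 0.455). The mean was 0.00734 (-0.45 to 0.404) in 100 simulations of unchanged groups. With all 8 libraries in both comparisons the correlation was -0.304 against -0.491 (-0.821 to 0.101) simulated. Of 1286 cue genes there (by unadjusted p, not edgeR's 2175), 87.6% went the other way with CBD, against 88.4% in simulations. Of cue genes picked anew in each split, 1116 on average, 45% did so. An opposite direction of the CBD and cue effects beyond that given by the shared libraries was not detected across genes.

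The effect of CBD without the anxiety cue was read from CBD against vehicle libraries with the neutral cue. These vehicle libraries are also the neutral-cue side of the cue comparison, so changes found in both are not independent. Oligodendrocyte and myelin genes fell, with a median log2 fold change of -0.391, 20 of 21 below 0 and 19 members past the threshold adjusted over the list alone. Camera gave adjusted p = 1.54e-10, and adjusted p = 0.409 with an estimated correlation. Mbp, the myelin basic protein gene, was 3705 ± 475 CPM with vehicle and 2642 ± 572 CPM with CBD (SD, n = 8; -0.49, SE 0.154). Mal was at -0.39 (SE 0.126). Gsn, the actin-severing gelsolin, was at -0.84 (SE 0.201). It was at -0.221 with liver and fat covariates, where Mal stayed at -0.386. With the other composition covariates the list was at -0.0834 and still passed (camera adjusted p = 0.00738), with Mbp at -0.189, Mal at -0.204 and Gsn at -0.63.

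Other glial markers fell beside them with CBD in neutral-cue libraries. Oligodendrocyte precursor markers had a median of -0.271, 12 of 12 below 0 and 4 past the threshold adjusted over the list alone. The lineage factors Olig2 and Olig1 were among these 4, at -0.52 (SE 0.130) and -0.44 (SE 0.120). Astrocyte markers had a median of -0.185, 17 of 20 below 0 and 6 adjusted over the list alone, and microglia markers -0.211, 20 of 21 below 0. Camera adjusted p for precursors, astrocytes and microglia were 2.82e-05, 0.000409 and 0.000172, and adjusted p = 0.409, 0.415 and 0.409 with an estimated correlation. With composition covariates the medians were -0.0073 for precursors (camera adjusted p = 0.577), -0.0404 for astrocytes (0.53) and -0.11 for microglia (0.107). Olig2 was at -0.164 and Olig1 at -0.151 in that fit. Liver and fat covariates left the precursor median at -0.17.

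Neuronal markers moved in neutral-cue libraries too. Medium spiny neuron markers rose with CBD with a median of 0.506, 28 of 29 above 0 (camera adjusted p = 4.41e-08; adjusted p = 0.415 with an estimated correlation). Bcl11b was at 0.51 (SE 0.204) and Drd1 at 0.57 (SE 0.291). Septal, pallidal and islands of Calleja markers fell with a median of -0.756, 14 of 20 below 0 and 9 adjusted over the list alone, and interneuron markers with -0.48, 13 of 20 and 10. Camera adjusted p of these lists were 0.0138 and 0.0175, with adjusted p = 0.409 for each with an estimated correlation. Lhx8, a factor of pallidal and cholinergic neurons, was at -1.42 (SE 0.389). The interneuron median was -0.306 without vehicle library 4. These calls ended with composition covariates, with medians of -0.0998 for medium spiny neurons (camera adjusted p = 0.105), -0.0579 for interneurons (0.633) and, with the other covariates, -0.183 for the septal list (0.31). With liver and fat covariates added, medium spiny neuron markers fell instead (-0.137, 0.0258). The composition fit put Drd1 at -0.0614, Bcl11b at 0.0203 and Lhx8 at -0.449.

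Immediate early genes rose with CBD in neutral-cue libraries with a median of 0.5, 24 of 30 above 0 (camera adjusted p = 0.00751; adjusted p = 0.491 with an estimated correlation). The median was 0.16 without CBD library 6 and the call ended (adjusted p = 0.298). Egr1 was at 0.69 (SE 0.258). Arc was at 0.80 (SE 0.402), and at 0.47 without that library, while Fos was at -0.050 (SE 0.278). Cortical and amygdalar glutamatergic markers had a median of 0.383 and did not pass (camera adjusted p = 0.0908). Their 2 members past the threshold adjusted over the list alone were Slc17a7 (4.49, SE 1.18) and the cholecystokinin gene Cck (2.19, SE 0.607). Both rested on CBD library 6, without which they were at 1.06 and 0.24. Fos lay between -0.418 and 0.0853 over removals of 1 library, and turned with liver and fat covariates (0.121). The immediate early median with composition covariates was -0.0482 (camera adjusted p = 0.226). Egr1 was then at 0.00197, Arc at -0.179, Slc17a7 at -0.309 and Cck at 0.217.

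Of the mitochondrial lists 4 fell with CBD in neutral-cue libraries, and import and dynamics (-0.0548, camera adjusted p = 0.0533) did not pass. Complex I had a median of -0.133, 35 of 36 below 0, complexes II to V -0.14, 40 of 41, mitochondrial ribosomal proteins -0.0928, 61 of 75, and the tricarboxylic acid cycle -0.115, 20 of 22. Camera adjusted p were 8.82e-07, 5.34e-06, 1.02e-05 and 0.000303, and adjusted p = 0.415 for each with an estimated correlation. The 3 complex I genes past the threshold adjusted over the list alone included Ndufa8 (-0.35, SE 0.106). Sdhc (-0.28, SE 0.085) passed in this way in the list of the cycle. The medians of the first 3 lists were -0.0708, -0.0678 and -0.0454 without vehicle library 6. That of the cycle was -0.0639 without vehicle library 4 and -0.0465 with composition covariates, which put Sdhc at -0.123 and Ndufa8 at -0.169.

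Some lipid and stress lists fell with CBD in neutral-cue libraries, while beta oxidation (-0.0183, camera adjusted p = 0.215) and glucocorticoid responsive genes (-0.146, 0.0908) did not pass. Polyunsaturated fatty acid metabolism had a median of -0.146, 26 of 38 below 0 (camera adjusted p = 0.00827; adjusted p = 0.409 with an estimated correlation), and 4 members passed adjusted over the list alone. They included the desaturase gene Fads3 (-0.48, SE 0.154) and the prostaglandin D synthase gene Ptgds (-0.48, SE 0.154). Scd2, also among them, was at -0.25 (SE 0.081). The list's median was -0.0965 without vehicle library 4 and -0.0352 with composition covariates (camera adjusted p = 0.112), which put Fads3 at -0.215, Ptgds at -0.0866 and Scd2 at -0.103. The oxidative stress list had a median of -0.151, 22 of 29 below 0 (camera adjusted p = 0.000408; adjusted p = 0.409 with an estimated correlation). Its 2 members past the threshold adjusted over the list alone were Gpx3 (-1.71, SE 0.390) and Ucp2 (-0.60, SE 0.161). The oxidative stress median was -0.0701, and Gpx3 at -0.536, in that fit. Fads3 was at -0.122 and Ucp2 at -0.297 with liver and fat covariates, where 5 vehicle and 0 CBD libraries were high in Plin1.

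Chaperones (-0.136, 24 of 28 below 0), cytosolic ribosomal proteins (-0.142, 59 of 60), cholesterol synthesis (-0.138, 17 of 22) and inflammatory genes (-0.112, 23 of 29) fell in that comparison too. Camera adjusted p, in this order, were 0.000172, 3.08e-06, 0.00827 and 0.0141, and adjusted p = 0.415, 0.491, 0.53 and 0.415 with an estimated correlation. The ribosomal call ended without vehicle library 6 (-0.0315, adjusted p = 0.182) and the inflammatory one without vehicle library 2 (0.0878). The cholesterol call ended without vehicle library 4 (-0.0524, 0.234) or 8 (0.0556), and its median was -0.215 without CBD library 6. Composition covariates ended it too (-0.0845, adjusted p = 0.226), and ended the inflammatory call (0.287). The endocannabinoid list did not pass as a group (median -0.0254, 16 of 29 below 0, camera adjusted p = 0.981), although 11 members passed adjusted over the list alone. Abhd4, of anandamide synthesis, and Naaa, which hydrolyses acylethanolamines, were at -0.27 (SE 0.076) and -0.26 (SE 0.086), but at -0.12 and -0.151 with composition covariates.

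Among single genes edgeR called 0 for CBD with the neutral cue, with 3852 at an unadjusted p under 0.05 (1798 higher and 2054 lower) and 324 at an adjusted p under 0.1. DESeq2 called 382 and voom with quality weights 1. Of the 382 DESeq2 kept 1 with liver and fat covariates (1 call), 7 with composition covariates (29 calls) and 1 with both (33 calls). Without libraries high in Slc17a6 or Plin1 edgeR called 31 and 2761. Mfng, a glycosyltransferase of Notch signalling, was 7.42 ± 2.11 and 3.31 ± 0.835 CPM (-1.16, SE 0.220). Its adjusted p was 0.0697 in edgeR, 0.00103 in DESeq2, 0.0046 in voom with quality weights and 0.0437 in edgeR on the 16 libraries compared. Also at 0.0697 was Slc25a47, a mitochondrial carrier of liver (4.66, SE 0.939). It was at 2.99 without CBD library 3 and at 1.23 with liver and fat covariates. At the same adjusted p the synuclein gene Sncg was at -3.17 (SE 0.656). So placed too was the adipocyte gene Trarg1 (-1.72, SE 0.360). In this comparison 4 of 8 CBD libraries and 0 of 8 vehicle libraries were high in Alb, and 0 and 5 were high in Plin1. With liver and fat covariates Sncg was at -1.52 and Trarg1 at -0.725, and with composition covariates Mfng was at -0.631 and Sncg at -1.87. Of the 38 genes picked for naming in this comparison, 30 moved by over 1.5 times or turned with composition covariates, and 9 did so with liver and fat covariates. The edgeR count at unadjusted p was 2398 without vehicle library 4 and 905 with composition covariates. Without vehicle anxiety-cue library 5 or 4, which enter the shared estimate of spread, edgeR called 165 and 68 genes.

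**Figure D3:**
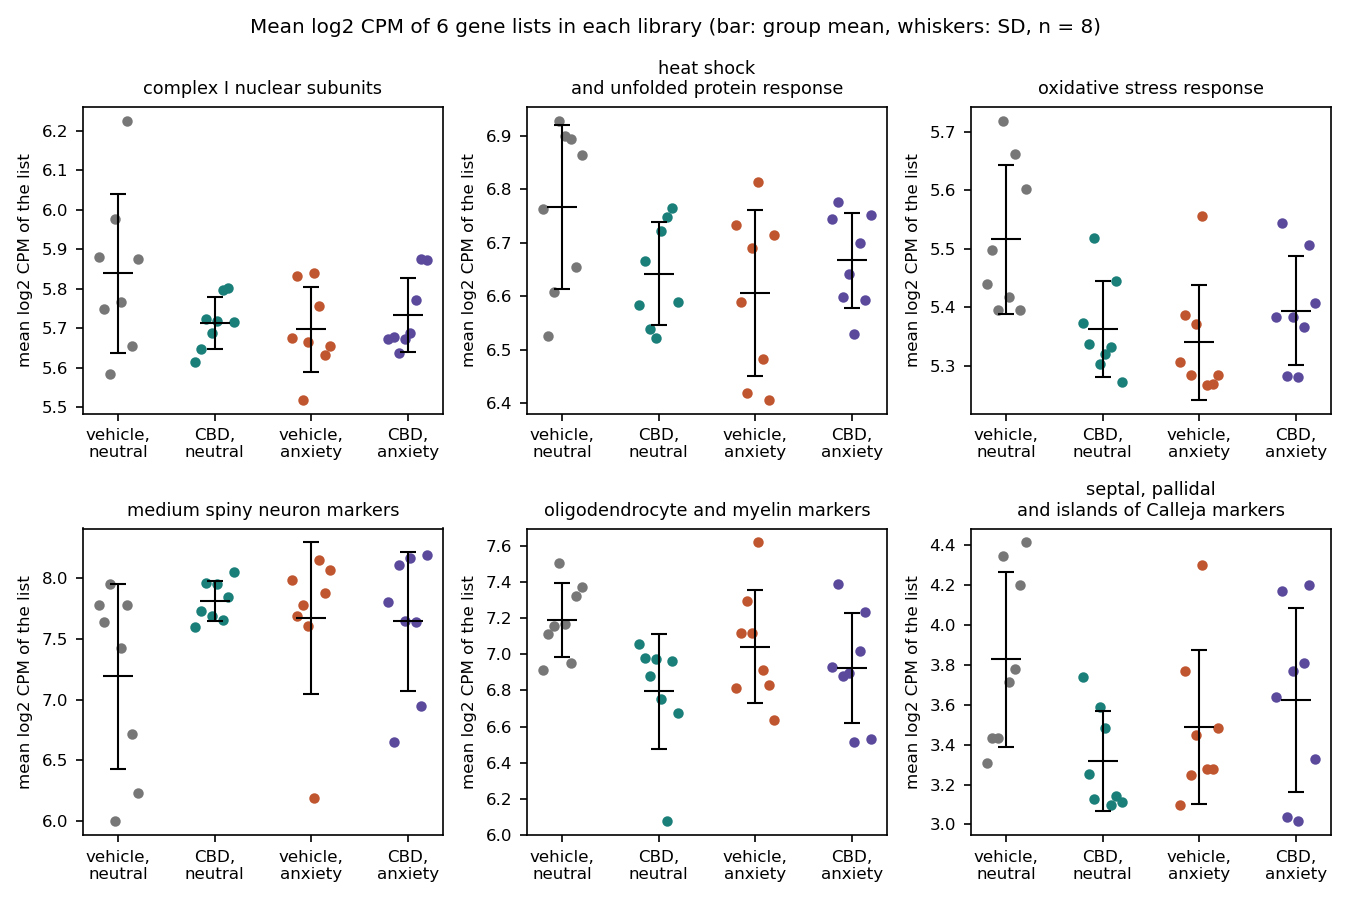
Mean log2 CPM of 6 gene lists in each of the 32 libraries (1 point per library; bar, group mean; whiskers, SD, n = 8). The highest complex I value is that of a vehicle neutral-cue library.

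The effect of the anxiety cue under CBD was read from CBD libraries, anxiety cue against neutral cue. Oligodendrocyte and myelin markers rose with a median log2 fold change of 0.142, 20 of 21 above 0 (camera adjusted p = 0.00215; adjusted p = 0.917 with an estimated correlation). Hapln2, of the node of Ranvier, was 71.7 ± 14.5 CPM with the neutral cue and 87.3 ± 21 CPM with the anxiety cue (SD, n = 8; 0.28, SE 0.167). This call ended without neutral-cue library 6 (0.0681, adjusted p = 0.389) or anxiety-cue library 2 (0.0714, 0.105), and the median was 0.0885 without anxiety-cue library 7. Endothelial and mural markers rose with a median of 0.0665, 18 of 22 above 0 (camera adjusted p = 0.0123; adjusted p = 0.917 with an estimated correlation). With the other composition covariates oligodendrocyte markers fell instead (-0.0761, camera adjusted p = 0.000401), with Hapln2 at -0.023, and liver and fat covariates left the endothelial median at 0.0252.

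Inflammatory genes (0.0648, 23 of 29 above 0), septal, pallidal and Calleja markers (0.316, 13 of 20) and mitochondrial ribosomal proteins (0.028, 49 of 75) rose too with the cue under CBD. Camera adjusted p were 0.0302, 0.0401 and 0.0472, with adjusted p = 0.917 for each with an estimated correlation. Lhx8 was at 0.90 (SE 0.387). The endothelial, inflammatory, septal and mitochondrial ribosomal calls held in 27, 26, 23 and 16 of 32 removals of 1 library. Their highest adjusted p were 0.188 without neutral-cue library 6, 0.105 without anxiety-cue library 2, 0.159 without anxiety-cue library 7 and 0.377 without neutral-cue library 1. The endothelial median ranged over removals from 0.0348 without neutral-cue library 2 to 0.108 without neutral-cue library 4. Without anxiety-cue library 2 the inflammatory median was 0.0352 and the septal 0.137, but the inflammatory was 0.0985 without library 3 of that group and 0.0991 without neutral-cue library 7, and the mitochondrial ribosomal median was 0.013 without anxiety-cue library 7. In the composition fit the septal call ended (0.167, adjusted p = 0.136), with Lhx8 at 0.45, and the mitochondrial ribosomal median 0.0474.

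Cortical and amygdalar glutamatergic markers fell with the anxiety cue in CBD libraries, with a median of -0.389 and 14 of 17 below 0 (camera adjusted p = 0.0123; adjusted p = 0.917 with an estimated correlation). They did not pass without neutral-cue library 6 (-0.128, adjusted p = 0.141). Slc17a7 was at -3.71 (SE 1.13) and Cck at -2.54 (SE 0.617). Leaving that library out put them at -0.26 and -0.58, and the other composition covariates at -0.03 and -0.946, with the list at -0.207 (0.0976). Medium spiny neuron markers fell with a median of -0.0804, 25 of 29 below 0 (camera adjusted p = 0.0373; adjusted p = 0.917 with an estimated correlation), a call that held in 25 of 32 removals. The median was 0.0232 without anxiety-cue library 2 (0.784), 0.000147 without anxiety-cue library 7 (0.434) and -0.0292 without neutral-cue library 8 (0.116), and at its lowest -0.167 without anxiety-cue library 5. With composition covariates these markers rose instead (0.193, camera adjusted p = 3.51e-05).

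Beta oxidation fell with the cue under CBD with a median of -0.0776, 16 of 24 below 0 (camera adjusted p = 0.019; adjusted p = 0.917 with an estimated correlation). Hadh was at -0.53 (SE 0.197). Without neutral-cue library 3 Hadh was at -0.18 and the list's median at 0.00628 (adjusted p = 0.753). The call also ended without neutral-cue library 1 (0.0593) or anxiety-cue library 3 or 5 (0.0614 and 0.0699). Complex I (0.0258, camera adjusted p = 0.305), complexes II to V (0.0237, 0.197) and polyunsaturated fatty acid metabolism (0.00284, 0.328) did not pass, nor did immediate early genes (-0.132, 0.197) and interneuron markers (0.271, 0.168). Cox4i1 was at 0.033 (SE 0.082), and between -0.000852 and 0.0596 over removals of 1 library. The GABA synthesis gene Gad1 was at 0.23 (SE 0.077, and 0.13 with composition covariates). Fads2, the delta-6 desaturase that acts on linoleic acid, was at -0.43 (SE 0.156, but -0.14 without neutral-cue library 3).

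For single genes of the cue under CBD edgeR called 0, with 672 at an unadjusted p under 0.05 (281 higher and 391 lower, 853 expected by chance). DESeq2 and voom with quality weights called 0, but DESeq2 called 21 with composition covariates and 40 with liver and fat added. At the smallest p, each with an adjusted p of 0.995, stood Cck (-2.54) and the lipid transporter gene Abca6 (-1.03, SE 0.247). Prdm8 was at -3.66 (SE 0.909), but at -0.64 without neutral-cue library 6 and at -0.142 with composition covariates.

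Whether the effect of CBD depended on the cue was tested by the interaction, the CBD effect with the anxiety cue minus that with the neutral cue. Of 30 lists 17 passed, 16 of them upward. Complex I differed by a median of 0.163 on the log2 scale, 36 of 36 above 0, complexes II to V by 0.181, 40 of 41, mitochondrial ribosomal proteins by 0.128, 66 of 75, and the tricarboxylic acid cycle by 0.126, 21 of 22. Camera adjusted p were 4.02e-07 for the first 3 and 0.000419 for the cycle, and adjusted p = 0.447 for each with an estimated correlation. The interaction was 0.41 (SE 0.150) for Ndufa8 and 0.33 (SE 0.119) for Sdhc. Mitochondrial import and dynamics (0.0932, 23 of 36 above 0) passed narrowly (camera adjusted p = 0.0481; adjusted p = 0.447 with an estimated correlation). That call held in 15 of 32 removals, with the highest adjusted p at 0.233 without vehicle neutral-cue library 6. The same removal put complexes II to V at 0.0918 and mitochondrial ribosomal proteins at 0.073, and removing vehicle neutral-cue library 4 put the cycle at 0.0739. The cycle no longer passed with composition covariates (0.0511, adjusted p = 0.0607), where Sdhc and Ndufa8 were at 0.153 and 0.227.

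Chaperones (0.214, 25 of 28 above 0), the oxidative stress list (0.18, 23 of 29), cytosolic ribosomal proteins (0.172, 60 of 60), inflammatory genes (0.2) and cholesterol synthesis (0.179) also had positive interactions. Camera gave adjusted p = 1.87e-06, 0.000167, 7.26e-06, 0.0167 and 0.00884, and adjusted p = 0.447, 0.447, 0.566, 0.447 and 0.566 with an estimated correlation. Ucp2 was at 0.93 (SE 0.227). The ribosomal call ended without vehicle neutral-cue library 6 (0.0587, adjusted p = 0.0699) and the cholesterol call without vehicle neutral-cue library 4 (0.0916, 0.125). The inflammatory call ended without vehicle neutral-cue library 2 (0.0726), and its median was 0.131 without CBD anxiety-cue library 5. Composition covariates put chaperones at 0.13, the oxidative stress list at 0.114, cytosolic ribosomal proteins at 0.29 and cholesterol synthesis at 0.0473 (adjusted p = 0.839). Polyunsaturated fatty acid metabolism (0.121, 24 of 38 above 0, camera adjusted p = 0.0572) and the endocannabinoid list (0.0394, 0.711) did not pass.

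Among cell type markers, medium spiny neurons had a negative interaction (-0.494, 29 of 29 below 0). It turned positive past the threshold with composition covariates (0.19, camera adjusted p = 0.0177), and with liver and fat covariates added (0.192, 0.00507). Positive ones were found for oligodendrocytes (0.277, 20 of 21 above 0), their precursors (0.236), astrocytes (0.243, 17 of 20), microglia (0.183), the septal and pallidal list (0.794, 13 of 20) and interneurons (0.645, 14 of 20). Camera adjusted p, in this order, were 1.47e-06, 0.000132, 0.00297, 0.000577, 0.0167, 0.0167 and 0.0213, with adjusted p = 0.447 for each with an estimated correlation. Lhx8 was at 1.61 (SE 0.542) and Bcl11b at -0.62 (SE 0.289), but at 0.804 and -0.0812 with composition covariates. That fit ended the calls for precursors (0.0118, adjusted p = 0.584), the septal list (0.409, 0.0697) and interneurons (0.0285, 0.97), and oligodendrocytes turned (-0.144, 0.00798). The microglia call ended without vehicle neutral-cue library 2 or CBD neutral-cue library 6 (adjusted p = 0.0561 and 0.0509). Its median was 0.115 without vehicle anxiety-cue library 1 and 0.117 without vehicle anxiety-cue library 6. That of the precursors was 0.13 without CBD anxiety-cue library 2 and 0.153 without CBD neutral-cue library 6.

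Single genes did not pass for the interaction in edgeR, which called 0 with 2353 at an unadjusted p under 0.05 (1197 higher and 1156 lower). DESeq2 called 14 and voom with quality weights 0. None of the 14 stayed with covariates, where DESeq2 called 0 (liver and fat), 16 (composition) and 29 (both). EdgeR called 1475 without libraries high in Plin1, a fit that kept only 3 vehicle neutral-cue libraries. At the smallest p in edgeR, each with an adjusted p of 0.321, were Mcub (2.24, SE 0.448), the galectin-related gene Grifin (3.04, SE 0.675) and the actin-capping gene Capg (2.84, SE 0.656). Metrnl (1.34, SE 0.309) and the extracellular matrix gene Postn (4.02, SE 0.936) followed, and all 5 were among the 14. Postn was at 2.67 without CBD anxiety-cue library 2. With liver and fat covariates Postn was at 2.14 and Capg at 1.76, and with composition covariates Grifin was at 1.88 and Metrnl at 0.891. Capg and Postn were high in 4 libraries, vehicle neutral-cue libraries 1, 2 and 3 and CBD anxiety-cue library 2. The edgeR count at unadjusted p was 1589 without vehicle neutral-cue library 4 and 1069 with composition covariates. It was 3940 without vehicle anxiety-cue library 5, which also gave 10 edgeR calls.

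Averaged over drug, 14 lists passed for the anxiety cue, 12 of them downward. For mitochondrial lists this averages falls with vehicle and medians slightly above 0 with CBD. Beta oxidation fell with a median of -0.119, 21 of 24 below 0, polyunsaturated fatty acid metabolism with -0.0789, 30 of 38, and cholesterol synthesis with -0.112, 22 of 22. Complex I fell with -0.0731, 32 of 36, and complexes II to V with -0.0587. Camera adjusted p of these 5 lists were 2.08e-07, 2.18e-05, 6.54e-06, 2.08e-07 and 4.94e-07, and adjusted p = 0.375, 0.239, 0.625, 0.625 and 0.636 with an estimated correlation. Chaperones (-0.0734, 22 of 28 below 0) and microglia markers (-0.109, 20 of 21) fell, and endothelial markers (0.0921, 17 of 22 above 0) and medium spiny neuron markers (0.177, 28 of 29) rose. For them camera adjusted p were 5.42e-07, 4.26e-06, 2.64e-06 and 0.00144, and adjusted p = 0.375, 0.375, 0.375 and 0.73 with an estimated correlation. Among the genes at the smallest p, each at an adjusted p of 1, was Tctn3 of the ciliary transition zone (0.45, SE 0.110). EdgeR called 0 genes with 619 at an unadjusted p under 0.05, and DESeq2 and voom with quality weights 0. DESeq2 called 21 with composition covariates and 36 with liver and fat added, and edgeR 109 without libraries high in Plin1. The edgeR count was 1061 without vehicle anxiety-cue library 5. Without vehicle neutral-cue library 6 complex I was at -0.0405 and complexes II to V at -0.0345 (-0.0359 without vehicle anxiety-cue library 3), and without CBD neutral-cue library 3 beta oxidation was at -0.0736. Leaving out vehicle neutral-cue library 4 put polyunsaturated fatty acid metabolism at -0.0496 and cholesterol synthesis at -0.0652. Mitochondrial ribosomal proteins (-0.0433), the tricarboxylic acid cycle (-0.0333) and cytosolic ribosomal proteins (-0.0678) passed as well (camera adjusted p = 0.000124, 0.0336 and 7.05e-06; adjusted p = 0.691, 0.73 and 0.73 with an estimated correlation). These 3 calls ended without vehicle neutral-cue library 6 (0.239, 0.205 and 0.804), and that of the cycle without other single libraries (highest 0.587; median -0.0591 without vehicle neutral-cue library 2) and with composition covariates (-0.0126, 0.341). The medium spiny neuron call ended without vehicle neutral-cue library 4 (0.118, adjusted p = 0.176) or 8 (0.0706). The composition fit gave -0.0363 for complexes II to V, -0.0675 for cholesterol synthesis, -0.0691 for microglia and 0.079 for medium spiny neurons.

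Averaged over cue, CBD went with lower oligodendrocyte genes, and 15 lists passed, 13 of them downward. The medians of complex I, polyunsaturated fatty acid metabolism and medium spiny neurons had opposite signs with the 2 cues. Oligodendrocyte and myelin markers fell with a median of -0.265, 20 of 21 below 0 and 15 past the threshold adjusted over the list alone, and precursor markers with -0.164, 12 of 12 and 3. Camera gave these adjusted p = 2.35e-16 and 4.69e-06, and adjusted p = 0.455 for each with an estimated correlation. Microglia markers (-0.109, 18 of 21 below 0), polyunsaturated fatty acid metabolism (-0.0545, 29 of 38), complex I (-0.0491, 30 of 36) and glucocorticoid responsive genes (-0.108, 15 of 23) fell as well. Their camera adjusted p were 1.74e-05, 0.00743, 0.000379 and 0.0189, and adjusted p = 0.455, 0.455, 0.629 and 0.629 with an estimated correlation. Medium spiny neuron markers (0.243, 27 of 29 above 0) and immediate early genes (0.233, 28 of 30) rose (camera adjusted p = 8.43e-07 and 0.000379; adjusted p = 0.629 for each with an estimated correlation). At the smallest p, each with an adjusted p of 0.271, were Zfp438 (-0.27, SE 0.059) and 4 genes of fat or muscle. These were Adipoq (-3.08, SE 0.704), Lgals12 (-2.92, SE 0.670), Adrb3 (-2.81, SE 0.657) and Tmem182 (-2.36, SE 0.517), where high Plin1 was found in 8 vehicle and 2 CBD libraries. With liver and fat covariates these 4 were at -0.206, -0.708, 0.124 and -0.791. EdgeR called 0 genes with 1240 at an unadjusted p under 0.05, DESeq2 8 and voom with quality weights 0. With covariates DESeq2 kept 0 of the 8 and called 16 (composition), 2 (liver and fat) and 26 (both). The edgeR count was 798 without vehicle anxiety-cue library 5 and 1918 without CBD anxiety-cue library 2. Removing vehicle anxiety-cue library 4 gave 61 edgeR calls. The complex I call ended without vehicle neutral-cue library 6 (-0.022, adjusted p = 0.155), and the immediate early median was 0.129 without CBD neutral-cue library 6. That of glucocorticoid responsive genes ended without vehicle neutral-cue library 5 or 6, vehicle anxiety-cue library 3 or CBD neutral-cue library 6 (adjusted p = 0.0503, 0.0717, 0.0745 and 0.086), and liver and fat covariates left its median at -0.0313. Composition covariates ended these calls, except those of complex I and of oligodendrocytes (-0.174, adjusted p = 1.95e-16), with adjusted p from 0.326 for glucocorticoid responsive genes to 0.935 for medium spiny neurons (-0.00583), immediate early genes (0.0256) and precursors (-0.0145).

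Across the 7 comparisons the camera calls rest on the preset correlation of 0.01 between genes, and none held with an estimated correlation. The fry test gives a directional p, for genes that move on balance one way, and a mixed p, for change in either direction, and neither compares the list with other genes. The smallest adjusted directional p was 0.0584, for the cue in vehicle libraries. The mixed p passed for chaperones with the cue in vehicle libraries (adjusted p = 0.0489). For CBD with the neutral cue it passed for the polyunsaturated fatty acid, oxidative stress and endocannabinoid lists among others (0.0233 for each). Exact permutation tests of each list's mean level per library, over 12870 assignments of 8 against 8, passed for no list. Their smallest adjusted p were 0.286 for the cue with vehicle, 0.853 for CBD with the anxiety cue, 0.0786 for CBD with the neutral cue and 0.856 for the cue with CBD. The value of 0.0786 was shared by 5 lists. Their mean levels differed by -0.393 for oligodendrocyte and myelin markers (unadjusted p = 0.00326, the smallest), -0.284 for precursors, -0.154 for oxidative stress, -0.51 for the septal and pallidal list and -0.341 for interneurons.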

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

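The tests of tissue composition and of 1 library for the respiratory chain genes, the tests of liver and fat transcripts in 20 libraries, the composition test of the DESeq2 calls, and the settings with liver and fat covariates were chosen after the result was seen. The other tests here were set down before their values were seen, but the test of the DESeq2 calls against the liver or fat score uses lists chosen after their values were seen.

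Single libraries stood apart from the other 7 of their group in 44 of 381 tests of lists and named genes by Dixon's ratio of gap to range. Chance gives about 1 in 20 groups, or 19 here. Vehicle anxiety-cue library 5 was apart in 12 of them. It was lowest for medium spiny neuron markers (ratio 0.724) and for Adcy5 (0.732), Bcl11b (0.709), Drd1 (0.698) and Drd2 (0.794), and highest for the oxidative stress list (0.584), cholesterol synthesis (0.539), astrocyte markers (0.602), Cnr1 (0.545), Gpx3 (0.55), Lhx8 (0.708) and Metrnl (0.587). CBD neutral-cue library 6 was also apart in 12. It was lowest for oligodendrocyte markers (0.613), Hapln2 (0.602), Mal (0.634), Mbp (0.557), Mobp (0.601) and Olig2 (0.554), and highest for synaptic vesicle genes (0.747), dopamine, serotonin, GABA and glutamate signalling (0.658), cholesterol synthesis (0.626), Cck (0.57), Dab1 (0.584) and Fos (0.56).

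CBD neutral-cue library 3 was highest for beta oxidation (0.543), polyunsaturated fatty acid metabolism (0.543), Fads2 (0.703) and Hadh (0.685), and vehicle neutral-cue library 4 for polyunsaturated fatty acid metabolism (0.543) and Grifin (0.553). Rpph1 was highest in vehicle neutral-cue library 8 (0.716) and Nup214 lowest in vehicle neutral-cue library 6 (0.569). Sex-linked genes were lowest in vehicle neutral-cue library 2 (0.648), as was Tctn3 (0.555), and in vehicle anxiety-cue library 2 (0.617). Slc17a7 and Cck were highest in CBD anxiety-cue library 3 (0.62 and 0.553), and microglia markers in CBD anxiety-cue library 2 (0.608). Haemoglobin genes were lowest in CBD anxiety-cue library 5 (0.577), Ptges in CBD anxiety-cue library 8 (0.562), Ndufc1 in vehicle anxiety-cue library 3 (0.599), Capg in CBD neutral-cue library 2 (0.595) and Zfp707l1 in CBD neutral-cue library 4 (0.54), while Ndufa12 was highest in CBD neutral-cue library 7 (0.559).

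Camera with the preset correlation called an interaction of CBD and cue in 17 lists. These were complex I, complexes II to V and mitochondrial ribosomal proteins (adjusted p = 4.02e-07 for each), the tricarboxylic acid cycle (0.000419) and mitochondrial import and dynamics (0.0481). They also were cytosolic ribosomal proteins (7.26e-06), medium spiny neurons (1.47e-06), chaperones (1.87e-06), oxidative stress (0.000167), inflammatory genes (0.0167) and cholesterol synthesis (0.00884). Cell type lists were astrocytes (0.000577), oligodendrocytes (0.000132), their precursors (0.00297), microglia (0.0167), the septal and pallidal list (0.0167) and interneurons (0.0213). The smallest adjusted p was 0.447 with an estimated correlation.

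The first pattern weighed is the lower level of 77 respiratory chain genes in vehicle libraries with the anxiety cue (median log2 fold change -0.16, quartiles -0.196 and -0.106, 76 of 77 below 0). With tissue composition covariates the median was -0.151 (quartiles -0.204 and -0.0883), which argues against composition as the whole cause. A single library may carry part of it: without vehicle neutral-cue library 6 the median was -0.0972 (-0.12 and -0.0468). A factor per library shared with cytosolic ribosomal protein genes also stays open, since with their level as a covariate the median was -0.091 (-0.122 and -0.0425); for both, the quartiles span the limit of 0.5 times the size (the use of quartiles was settled after the values were seen). An effect of the cue itself stays open too, and was not separated from these.

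The second pattern is the presence of liver or fat transcripts in 20 libraries. Rat liver RNA as the source is argued against by its abundant transcripts: in 0 of the 10 libraries with high Alb was the sum of Ahsg, Apoa1 and Serpina1 above that of every other library (1.54 to 3.08 against 1.38 to 3.88 CPM). A response to CBD as the whole cause is argued against by 10 libraries, 2 of vehicle with high Alb and 8 of CBD without. A part for the drug is not excluded, since 8 of 10 libraries with high Alb were of CBD and 8 of 10 with high Plin1 of vehicle (Fisher's exact test, 2-sided, p = 0.0538 for each). In the order of the title numbers the libraries with Alb and those with Plin1 made 20 runs, the most possible for 10 and 10 (exact p = 1.08e-05 over all orders). A source tied to that order could give this, but the labels do not say what the title numbers stand for. The drug nearly alternates in that order too, as all 16 CBD libraries have even and all 16 vehicle libraries odd title numbers, and it makes 17 runs over these 20 libraries. With the kinds placed anew only within each drug, 1 of 2025 placements, the real one, gave 20 runs (exact p = 0.000494; highest other 19), and the 3 pairs of neighbours with the same drug were of different kinds. Order and drug are otherwise confounded in most of these libraries, and the source was not tested.

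The third pattern is the 382 genes that DESeq2 called for CBD with the neutral cue, where edgeR called 0. Liver and fat transcripts may account for many. Of the calls, 42.9% went with the liver or fat score within groups, against 1.86% of the 19388 genes tested (38.6% and 1.71% outside the score's own lists), and 1 call was left with liver and fat covariates. Composition may account for part of the rest. Its covariates lowered the median absolute log2 fold change of the calls from 1.26 to 0.599 and left 29 calls, 7 of them shared. Within groups 33.2% of calls went with its score (24.7% of genes tested) and 76.2% with either score (26.5%). No call went with both. The same fit gave 16 to 21 calls in each of the other 6 comparisons, 4 of which had 0 without covariates, so most of the 29 are not a remainder of the 382. With both explanations in place, an effect of CBD itself stays open and was not separated from them.

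Other splits of the same libraries, 100 per comparison with the real one included, were drawn to ask whether chance can be excluded. For genes past the threshold the real count was 0 in all 7 comparisons, so 100 of 100 splits gave as many and nothing can be read from that. The highest other counts of such genes were 1880, 88, 224, 118, 0, 6 and 1406, for the comparisons in the order of Results. That leaves 14 counts, of which 0.7 would be expected to have fewer than 5 such splits by chance, and 2 did. For the cue in vehicle libraries 2 splits gave as many lists as the real 18 (highest other 18), and for CBD with the neutral cue 2 gave as many genes at unadjusted p as 3852 (highest other 3875). Chance can be excluded at 5 in 100 for each of these counts taken alone, but not over all 14, and another split equalled or passed the real one in both. Chance cannot be excluded for the other 12. For the cue in vehicle libraries 16 splits gave as many genes at unadjusted p as 2175 (highest other 5033), and for CBD with the neutral cue 6 gave as many lists as 18 (highest other 19). For CBD with the anxiety cue the numbers were 72 for genes at unadjusted p (real 270, highest other 3689) and 65 for lists (real 6, highest other 18). In the same form the cue in CBD libraries gave 31 (672, 2110) and 70 (8, 17), and the interaction 5 (2353, 3005) and 8 (17, 20). The mean cue effect gave 49 (619, 4141) and 26 (14, 19), and the mean CBD effect 18 (1240, 4708) and 14 (15, 18). Splits that call 1880 or 1406 genes, where the real ones call 0, point to a structure of the samples that the groups do not explain. Camera passed a median of 8 to 12 lists in other splits, so calls are common without the real groups. The real 6 and 8, for CBD with the anxiety cue and the cue in CBD libraries, were below their medians of 8 and 9.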

How the results depend on the processing

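The settings with liver and fat covariates, DESeq2 with any covariates, covariates without a list's own, those without 3 libraries or without libraries high in Alb, Plin1 or Slc17a6, and the removal of single libraries for the lists were chosen after the result was seen; the others were planned. Of the settings compared over the counts of genes, counts of lists and the correlation across genes, 589 left the result on the same side of its threshold or within 1.5 times, 23 moved a count or value further, 33 gave calls where there had been 0 and 14 took all calls away.

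Counts of genes past the threshold, 0 throughout in edgeR, rose in these settings. DESeq2 called 382 for CBD with the neutral cue, 14 for the interaction and 8 for the mean CBD effect. With tissue composition covariates DESeq2 called 16, 17, 29, 21, 16, 21 and 16, for the comparisons in the order of Results. Liver and fat covariates gave 0, 1, 1, 0, 0, 0 and 2 in this order, and both sets 33, 21, 33, 40, 29, 36 and 26. Voom with quality weights called 1, and the 16 libraries alone 4, for CBD with the neutral cue, and a term for low against high title numbers gave 1 for the mean CBD effect. Leaving out libraries high in Plin1 left vehicle neutral-cue libraries 6, 7 and 8, of which 7 and 8 were high in Slc17a6 and 6 and 8 among 3 libraries in doubt. There were then 2972 for the cue in vehicle libraries, 2761 for CBD with the neutral cue, 1475 for the interaction and 109 for the mean cue effect. Without libraries high in Slc17a6 there were 19 for the cue in vehicle libraries and 31 for CBD with the neutral cue, of which 14 were shared and lower in both. Those comparisons share their vehicle neutral-cue libraries, of which 3 of the 5 left were high in Gpnmb, Capg and Postn, genes among the calls. Leaving out 1 library at a time gave 0 to 165 for CBD with the neutral cue, 0 to 10 for the interaction, 0 to 61 for the mean CBD effect and 0 in the others. The cause was not tested for any of these.

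Counts of lists fell to 0 in all 7 comparisons with an estimated correlation, and again with fry. With tissue composition covariates they were 11 for CBD with the anxiety cue, 8 for CBD with the neutral cue and 7 for the mean CBD effect, and with liver and fat covariates added 11, 9 and 5; the 4 lists that are themselves covariates passed in none of these fits, by construction. With the other 3 covariates oligodendrocyte markers still passed for CBD with either cue, and turned the other way for the cue in CBD libraries (camera adjusted p = 0.000401) and the interaction (0.00798). Without 3 libraries in doubt (CBD neutral-cue 6, vehicle neutral-cue 6 and 8) they were 4 for the cue in CBD libraries and 8 for the mean CBD effect. Without libraries high in Slc17a6 there were 5 for the cue in CBD libraries. For the mean CBD effect there were 9 without libraries high in Alb and 6 with quality weights. Leaving out 1 library at a time gave 14 to 20, 2 to 10, 17 to 22, 2 to 12, 15 to 19, 11 to 17 and 9 to 19, in the order of Results. Medium spiny neuron markers turned the other way past the threshold for CBD with the neutral cue with all covariates (camera adjusted p = 0.0258). They did so for the cue in CBD libraries with composition covariates (3.51e-05), all covariates (1.87e-05) and without libraries high in Slc17a6 (5.82e-05), and for the interaction with composition covariates (0.0177) and all covariates (0.00507). The correlation across genes was -0.304 with all 8 shared libraries in both comparisons, which shares their chance values. Apart from that, the cause was not tested. Genes that changed by 1.5-fold were often missed in simulated data, and so were some at 2-fold, at the 1 depth simulated.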

Other observations

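All values in this part were chosen after they were seen, and the levels of single libraries set side by side here were not tested.

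Some genes of phagocytes and of the extracellular matrix were high together in 4 libraries, vehicle neutral-cue libraries 1, 2 and 3 and CBD anxiety-cue library 2. Gpnmb, a glycoprotein of lipid-laden macrophages and microglia, was 21.3 to 33.2 CPM in these and at most 8.88 CPM in the other 28 libraries, whose median was 6.46 CPM. Capg was 16.6 to 21.4 CPM against at most 8.17 CPM, the annexin gene Anxa1 14.5 to 23.7 against at most 8.61 CPM, and the matrix gene Postn 4.83 to 11.1 against at most 2.12 CPM. Vim, the intermediate filament of reactive glia and mesenchymal cells, was 89.7 to 107 CPM against at most 59.1 CPM. The preset microglia and macrophage list did not set the 4 libraries apart (mean log2 CPM 3.44 to 3.718, against 3.842 in vehicle anxiety-cue library 5). Capg and Postn are among the genes at the smallest p for the interaction. Without libraries high in Slc17a6 the genes called lower for CBD with the neutral cue included Gpnmb (adjusted p = 0.0066), Vim (0.0066), Capg (0.0109), Postn (0.0129) and Anxa1 (0.0194), and all but Anxa1 are listed for the cue in vehicle libraries as well. Of the 5 vehicle neutral-cue libraries left there, 3 are those named above.

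In the library with most liver transcripts some liver genes were high and others near 0. CBD neutral-cue library 3 held 226 CPM of Alb, 319 of the haem carrier gene Hpx, 161 of the urea cycle gene Cps1, 129 of the fatty acid binding gene Fabp1 and 79.2 of the fibrinogen gene Fgb. Ahsg was at 0 CPM there, Apoa1 at 0.739 and Serpina1 at 0.801. Vehicle neutral-cue library 4 held the most fat transcripts, with Plin1 at 42.6 and Adipoq at 21.2 CPM.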
